A study of Mus musculus with 24 samples.

How the data were processed

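RNA from the colon of 24 SCID mouse samples, 4 in each of 6 groups, was sequenced by the authors on an Ion Torrent instrument after poly(A) selection and RNase III fragmentation, per the labels' protocols. The deposited files give raw counts per gene symbol, 1 file per sample with 43280 symbols, on mm10 per the submitters' processing notes. The aligner, the counting tool and the annotation used for counting are not given in the sources used here. Whether strand or reads shared between gene copies were handled is not given either, so predicted genes, immunoglobulin genes and other gene families may hold reads of their relatives.

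Each count was used as deposited. In all, 27509 symbols had 1 count or more, and library totals were 3052940 to 10587555. Groups and replicates were taken from the sample that each file belongs to. A table of the whole series holds the same columns, but 16 of its 24 column names give another sample than the file with the same values. Summed counts of 7 T cell genes, which SCID mice without transferred cells should lack, were 0 to 12 in Normal and 398 to 664 in Vehicle by the samples' own files, and 0 to 373 in Normal and 4 to 393 in Vehicle by the table's names. The samples' own files were used. For 4 antibody libraries, Isotype replicates 3 and 4 and anti-TNF replicates 1 and 2, the counts cannot decide between both labellings. The table names Isotype replicates 3 and 4 as anti-TNF 1 and 2, just as it names Normal replicates 3 and 4 as Vehicle 1 and 2. That shared pattern favours the samples' own files there too, without settling the point. No pair of replicates was a duplicate, with a chi-square per gene of 5.38 to 59.9 for genes with a summed count of at least 20.

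Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, robust quasi-likelihood fits of all 24 libraries together and F tests per comparison, which left 14773 genes with a common dispersion of 0.0539 and a median prior df of 6.53. P-values were adjusted by Benjamini-Hochberg within each of 8 comparisons, with a threshold of 0.05. SEs are the absolute log2 fold change divided by the square root of F. Fitted log2 fold changes used a prior count of 0.125. A fold against a group at 0 is given as a lower bound from a floor of 3 counts over the group, and one against 1 to 3 counts as a ratio of normalised counts with a 95% exact counting interval.

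Of 34 gene lists fixed beforehand, 33 with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. Adjustment was over the 33 lists of a comparison. Calls adjusted over the list alone use the gene p-values of edgeR. The colitis score used log2 CPM with a prior count of 2 (0.5 as an alternative) and genes with an absolute log2 fold change of at least 1, and was tested by a two-sided exact permutation test adjusted over 4 comparisons. Transcript length and GC content came from GENCODE M21, which matched 40422 symbols, 39469 by the same symbol. Length trends were summarised over 5 bins, and offsets came from a lowess fit with a span of 0.3.

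Named genes followed a rule: per comparison, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, up to 4 members with the smallest p of each list, and in treatment comparisons Dusp6, Spry4, Etv4, Etv5, Tnf, Ifng, Il17a, Lcn2 and S100a8. Predicted and Riken genes were left out of the extremes. Where no gene passed, the 3 smallest p were named, and for Isotype against Vehicle and the difference of effects the 5 smallest. These rules, the lists, the tests and 8 kinds of alternatives were chosen before the data were examined: DESeq2 1.42.0, limma-voom with sample weights, RLE factors, library size only, no filter, a mean of at least 5 CPM, a fit of only the groups compared and the replicate number as a block, besides leaving out each library. Further alternatives were chosen after seeing the data: the table's column names, the libraries on which both labellings agree, offsets for length, GC or both, libraries thinned to 3052940 counts, omission of libraries above 1000 CPM of pancreas transcripts, and the counts of genes moved back and the list medians without each library.

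The labels number replicates alike in each group without saying what they share. For MEKi 0.3 against Vehicle, same-numbered libraries deviated together in all 4 pairs, with correlations of 0.126, 0.125, 0.167 and 0.184 against a threshold of 0.1. A fit with the replicate block gave the same count of 1 gene. That block holds 1 effect per number shared by all 6 groups, so it cannot remove a pairing confined to these groups. No paired fit of these groups alone was run. Detection was checked on simulated data with 200 changed genes per fit, with each gene drawn independently and no shifts of whole libraries. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not analysed here.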

Results

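Gene counts were measured by RNA sequencing of poly(A) RNA from mouse colon in 24 libraries, 4 in each of 6 groups. The Normal libraries came from untreated SCID mice, which lack mature T and B cells. In the other 5 groups, SCID mice received activated CD4+ T cells from BALB/c donors, a transfer that leads to colitis. The Vehicle group was given 0.5% methylcellulose. The MEKi 0.3 and MEKi 1 groups were given an inhibitor of MEK, the kinase directly upstream of ERK, by mouth in enteric microparticles at 0.3 or 1 mg/kg each day between days 17 and 27. The Isotype and anti-TNF groups were injected every 4 days, starting on day 17, with 0.1 mg per mouse of a control antibody or of an antibody against the cytokine TNFa. In the 5 groups given T cells, colons were taken on day 28. Library totals were 3052940 to 5358259 counts in Normal, 4102817 to 5271844 in Vehicle, 4034493 to 5840995 in MEKi 0.3, 3175698 to 4678256 in MEKi 1, 6139216 to 10587555 in Isotype and 6974099 to 8545019 in anti-TNF. Counting intervals and floors cover counting error only. The labels do not say that replicates are separate animals, so p-values here measure only the spread between these samples, which may be partly technical. Levels are given as mean ± SD as CPM, the counts of a gene scaled to a common library total (n = 4 per group), and log2 fold changes from edgeR ± SE. Coordinates are from GENCODE M21 on mm10.

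The comparison of Vehicle with Normal asked what the transferred T cells changed in mice given no drug. T cell transcripts, close to absent from Normal colon, were present in all 4 Vehicle libraries. Of 18 measured T cell genes, 17 rose over all genes and 17 adjusted over the list alone. Cd3g, a chain of the T cell receptor complex (chromosome 9, 44969572 to 44980431), rose from a mean of 0.147 CPM, 3 counts in all, to 18.8 ± 3.51 CPM. Its count ratio was 114, with a 95% counting interval of 38.9 to 558 (adjusted p = 6.21e-10). All 30 interferon-gamma response genes rose by both adjustments, with a median log2 fold change of 3.56. Among them, Tap1, which transports peptides for MHC class I, rose by 3.35 ± 0.25 (adjusted p = 1.33e-09). Of 10 MHC class II genes, 9 rose by both adjustments. Cd74, the class II invariant chain (chromosome 18, 60803848 to 60812652), rose from 392 ± 35.1 to 4182 ± 550 CPM, a log2 fold change of 3.42 ± 0.16 (adjusted p = 1.65e-13). Of 7 cytotoxic and NK cell genes, 6 rose over all genes and 7 adjusted over the list alone. These 4 lists also passed the camera test with an estimated correlation between genes, at adjusted p = 0.0118 for T cell, 0.0186 for interferon-gamma response, 0.000675 for MHC class II and 0.0221 for cytotoxic and NK cell genes.

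Transcripts of neutrophils and other myeloid cells were also higher in Vehicle. Of 16 neutrophil genes, 15 rose by both adjustments, with a median log2 fold change of 5.24, or 5.02 with genes at 0 in Normal held at their bound. S100a8, a calprotectin subunit (chromosome 3, 90668978 to 90670035), rose from 0.214 ± 0.318 CPM, 3 counts in all, to 211 ± 40.5 CPM, a count ratio of 1290 with a 95% counting interval of 441 to 6260 (adjusted p = 1.83e-05). Of 18 monocyte and macrophage genes, 14 rose, and of 25 TNF and NF-kB targets, 21 rose, with the same counts adjusted over the list alone. Examples were the chemokine gene Ccl2 at 3.66 ± 0.50 (adjusted p = 9.64e-06) and the adhesion molecule gene Icam1 at 3.01 ± 0.31 (adjusted p = 2.16e-07). Of 7 mast cell and eosinophil genes, 5 rose and 1 fell by both adjustments, and the mast cell protease gene Mcpt1 rose by 7.71 ± 1.07 (adjusted p = 2.61e-05). Of 7 T helper genes, 6 rose and 1 fell, and of 16 immediate early and EGF-family genes, 10 rose, again by both adjustments. Of 18 epithelial antimicrobial and defence genes, 13 rose and 5 fell by both adjustments. Lcn2, whose product binds bacterial siderophores, rose by 5.07 (adjusted p = 9.24e-05). Each list of this paragraph passed camera at the preset correlation and had adjusted p = 0.107 with an estimated correlation.

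Further lists passed at the preset correlation alone. All 26 cell cycle genes rose by both adjustments (adjusted p = 0.278 with an estimated correlation). All 7 B and plasma cell genes rose, and 13 of 23 type I interferon response genes rose, by both adjustments (adjusted p = 0.236 with an estimated correlation for each). Of 14 matrix proteases and inhibitors, 10 rose and 1 fell, or 12 and 1 adjusted over the list alone (adjusted p = 0.228 with an estimated correlation). The matrix protease gene Mmp7 had 3 counts in Normal and a count ratio of 826, with a 95% counting interval of 282 to 4010. Of 9 dendritic cell genes, 4 rose, or 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.228 with an estimated correlation). Of 16 unfolded protein and amino acid stress genes, 10 rose and 2 fell, or 11 and 2 adjusted over the list alone (adjusted p = 0.419 with an estimated correlation).

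Genes of differentiated epithelium, muscle and nerve were lower in Vehicle. Of 17 surface colonocyte genes, 13 fell and 1 rose, or 14 and 1 adjusted over the list alone (adjusted p = 0.224 with an estimated correlation). Slc26a3, the colonic chloride and bicarbonate exchanger (chromosome 12, 31390871 to 31473917), fell from 1621 ± 413 to 145 ± 14.0 CPM, a log2 fold change of -3.49 ± 0.62 (adjusted p = 0.000211). Of 15 goblet cell genes, 9 fell and 3 rose by both adjustments (adjusted p = 0.419 with an estimated correlation). Of 12 enteroendocrine genes, 9 fell by both adjustments, among them Chga at -2.80 ± 0.49 (adjusted p = 0.00018). Of 17 xenobiotic metabolism genes, 14 fell and 3 rose by both adjustments, among them the cytochrome P450 gene Cyp2c55, which fell from 164 ± 47.6 to 0.414 ± 0.154 CPM (adjusted p = 0.00179). The last 2 lists had adjusted p = 0.224 with an estimated correlation. Of 17 fatty acid oxidation and PPAR target genes, 15 fell and 1 rose, and all 12 smooth muscle genes fell, by both adjustments (adjusted p = 0.126 with an estimated correlation for each). The myosin kinase gene Mylk fell by 1.85 on the log2 scale (adjusted p = 2.06e-06). Of 13 enteric neuron and glia genes, 11 fell, and all 8 adipocyte genes fell, by both adjustments (adjusted p = 0.228 with an estimated correlation for each).

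The other lists did not pass in this comparison. Of 16 genes of ERK pathway output, 5 rose and 5 fell by both adjustments, with a median log2 fold change of 0.01 and a camera adjusted p of 0.897. Of 6 tuft cell genes 3 fell (camera adjusted p = 0.0917), of 13 crypt stem cell and Wnt target genes 2 rose and 3 fell (0.148), of 18 collagen and matrix genes 8 rose and 2 fell (0.279), and of 12 endothelium genes 1 rose and 2 fell (0.604), with the same counts adjusted over the list alone. None of 3 squamous epithelium genes (0.985) or 5 red blood cell genes (0.838) changed by either adjustment. Both measured skeletal muscle genes fell, too few for a list test. Of 9 pancreas genes, 6 rose, or 8 adjusted over the list alone (camera adjusted p = 0.348), with 7027 CPM of pancreas transcripts in Vehicle replicate 4. The other 3 Vehicle libraries held 0.85 to 2.92 CPM of them, below the 5.41 to 15.07 CPM of the Normal libraries.

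In all, 6853 of 14773 tested genes differed between Vehicle and Normal, 3416 higher and 3437 lower, and 3243 of them differed by more than 2-fold. Short transcripts weighed more in Vehicle libraries. With transcripts in 5 bins by length, the median of the longest bin minus that of the shortest was -0.38 ± 0.12 on the log2 scale in Vehicle and 0.18 ± 0.07 in Normal, and 6502 genes differed with a transcript length offset. Of these, 5727 were among the 6853. The Spearman correlation of log2 fold change with length was -0.268 across 12175 genes, which are not independent replicates.

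**Figure D1:**
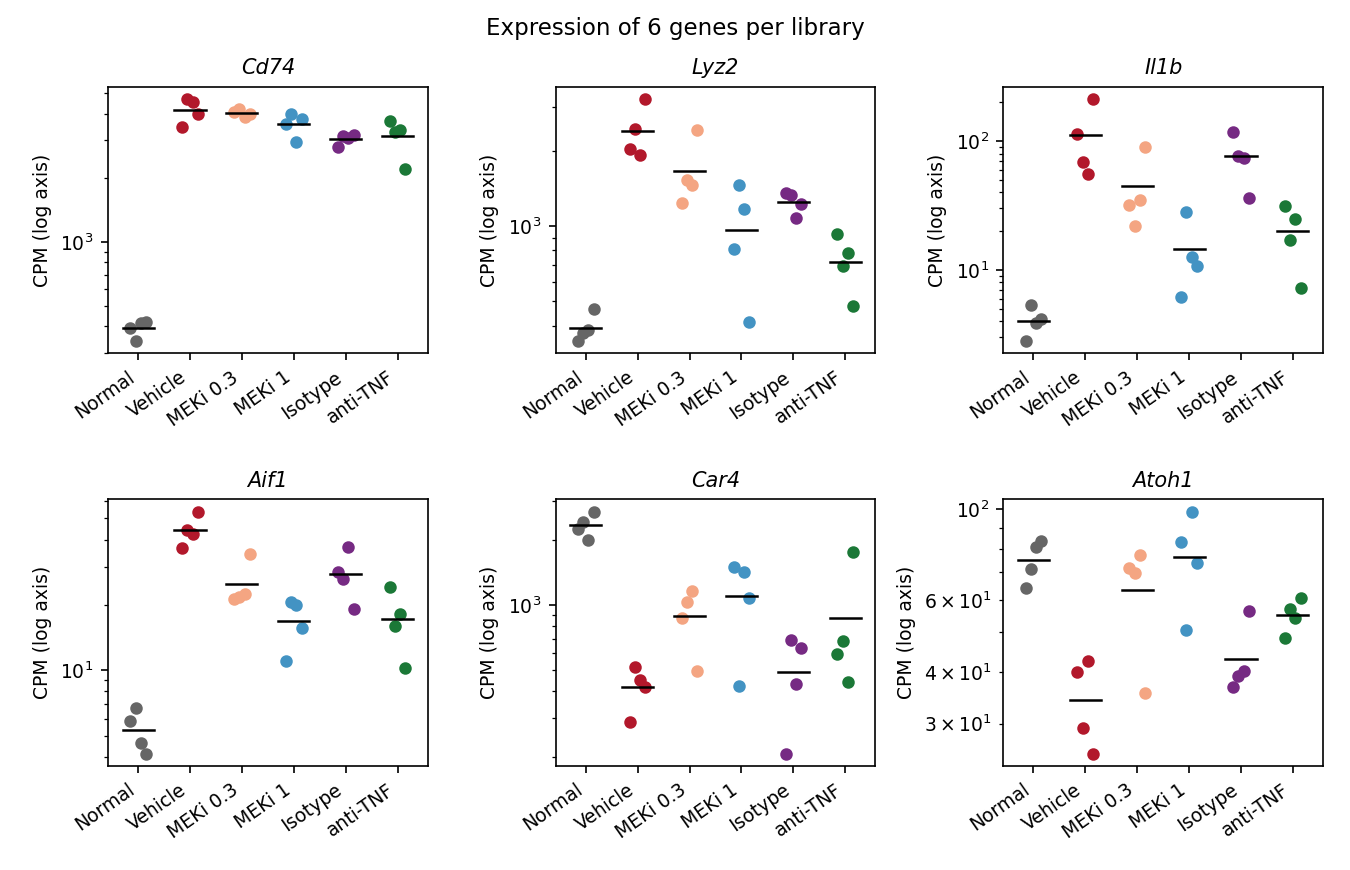
CPM on a log axis for 6 genes in the 4 libraries of each group, with 1 point per library and a bar at the group mean. Cd74 had a mean of 392 CPM in Normal and 4182 CPM in Vehicle, Aif1 fell from a mean of 44.2 CPM in Vehicle to 16.8 CPM in MEKi 1, and Atoh1 rose from 34.3 to 76.5 CPM.

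Isotype and Normal libraries were compared to ask the same question in the arm given a control antibody. S100a8 rose by a count ratio of 1330, with a 95% counting interval of 455 to 6460 (adjusted p = 1.9e-05). Ang4, an antimicrobial ribonuclease gene of the epithelium, fell from 37.9 ± 31.1 to 0.268 ± 0.196 CPM, a log2 fold change of -6.91 ± 1.42 (adjusted p = 0.000985). Of 18 T cell genes, 17 rose, or 18 adjusted over the list alone, and all 30 interferon-gamma response genes rose by both adjustments (adjusted p = 0.013 with an estimated correlation for each). All 12 smooth muscle genes fell by both adjustments (adjusted p = 0.109 with an estimated correlation). In all, 6085 genes differed, 3089 higher and 2996 lower. Of these, 2499 were also higher and 2280 also lower in Vehicle than in Normal, where independent lists would share 714.3 and 697.0, and 4 differed in opposite directions. The log2 fold changes of both comparisons had a Pearson correlation across genes of 0.937, against 0.527 for simulated unchanged groups sharing the same Normal libraries and 0.859 to 0.882 with the Normal libraries split between them. The covariance was 1.1, against 0.0447 in the simulations, a difference of 1.06. The simulations drew each gene independently and held no shifts of whole libraries, so unchanged real groups could correlate more strongly. Genes are not independent replicates.

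The comparison of Isotype with Vehicle set the control arms side by side. It gave 442 genes, 195 higher and 247 lower in Isotype, of which 108 differed by more than 2-fold. The 5 genes with the smallest p were lower in Isotype and included Med11, a Mediator subunit gene (chromosome 11, 70451919 to 70453727), at -1.17 ± 0.15 (adjusted p = 0.000242), and Rpl35, a ribosomal protein gene, at -1.28 ± 0.19 (adjusted p = 0.00138). The other 3, Gm14165, Gm15427 and Gm7206, are predicted genes that may share reads with near-identical copies, so their values are uncertain. Of 10 MHC class II genes, 0 changed over all genes and 6 were lower adjusted over the list alone, with a median log2 fold change of -0.42. That list was 1 of 4 that passed camera at the preset correlation, and all 4 had adjusted p = 0.967 with an estimated correlation. The count of 442 followed transcript length. The Spearman correlation of log2 fold change with length across 12175 genes, which are not independent replicates, was 0.543, and 29 genes differed with a length offset. Leaving out 1 library gave 188 genes without Isotype replicate 2, 128 without Isotype replicate 4, 263 without Vehicle replicate 1, 150 without Vehicle replicate 3 and 136 without Vehicle replicate 4.

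**Figure D2:**
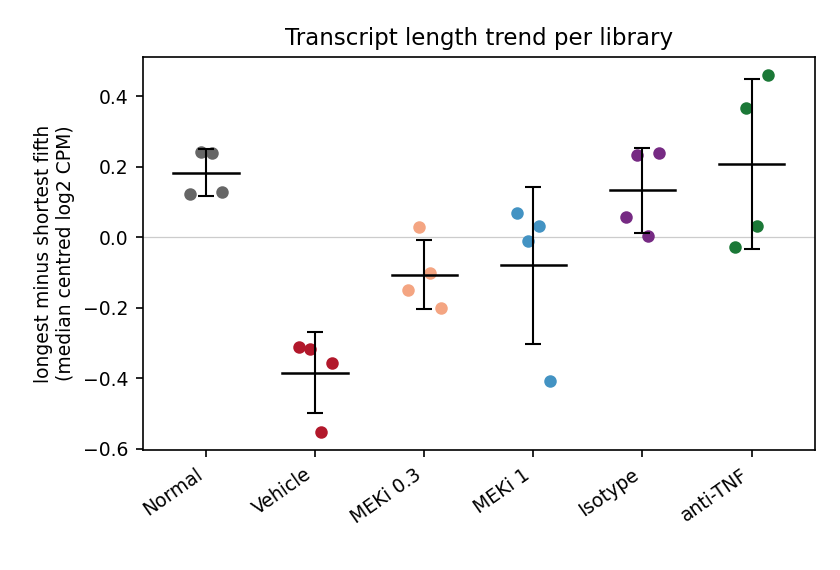
Median centred log2 CPM of the longest of 5 transcript length bins minus that of the shortest, with 1 point per library, bars at the group mean and error bars of 1 SD. Vehicle libraries had a mean of -0.38 and Isotype libraries a mean of 0.13.

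The higher inhibitor dose was compared with Vehicle to ask what the drug in its microparticles changed in the inflamed colon. Methylcellulose is recorded for Vehicle alone, and no group was given microparticles without the drug. Effects of MEK inhibition and of the carrier therefore cannot be told apart. Neutrophil transcripts were lower in MEKi 1. Of 16 neutrophil genes, 12 fell, or 13 adjusted over the list alone, with a median log2 fold change of -2.88. S100a9, the other calprotectin subunit, had a log2 fold change of -4.01 ± 1.08 (adjusted p = 0.0297). S100a8 passed too, with -2.98 to -2.27 when 1 library was left out, where it lost the threshold in 5 of 8 fits. Clec4e, a receptor for microbial glycolipids, changed by -4.31 ± 0.90 (adjusted p = 0.0115). Of 18 monocyte and macrophage genes, 10 fell, or 13 adjusted over the list alone. Aif1, a macrophage marker (chromosome 17, 35170991 to 35176068), fell from 44.2 ± 7.16 to 16.8 ± 4.49 CPM (log2 fold change -1.39 ± 0.25, adjusted p = 0.00673), and the lysozyme gene Lyz2 fell from 2408 ± 586 to 963 ± 451 CPM (adjusted p = 0.0114). Of 25 TNF and NF-kB targets, 9 fell, or 15 adjusted over the list alone. Il1b, a cytokine gene of activated myeloid cells (chromosome 2, 129364570 to 129371139), fell from 112 ± 70.5 to 14.4 ± 9.60 CPM, a log2 fold change of -2.94 ± 0.57 (adjusted p = 0.0112). Of 18 T cell genes, 9 fell, or 15 adjusted over the list alone, and the T cell kinase gene Lck changed by -1.07 ± 0.26 (adjusted p = 0.0182). These 4 lists passed camera at the preset correlation and had adjusted p = 0.292 with an estimated correlation.

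Some matrix genes were lower as well. Of 18 collagen and matrix genes, 8 fell, or 11 adjusted over the list alone, and Col1a1 changed by -1.24 ± 0.30 (adjusted p = 0.0198). The list had adjusted p = 0.339 with an estimated correlation. Of 14 matrix proteases and inhibitors, 3 fell, or 12 adjusted over the list alone (adjusted p = 0.293 with an estimated correlation). Mmp3, a matrix protease gene of stromal cells, changed by -3.90 ± 0.90 (adjusted p = 0.0171). Of 16 immediate early and EGF-family genes, 3 fell, or 4 adjusted over the list alone (adjusted p = 0.375 with an estimated correlation), among them the urokinase receptor gene Plaur at -2.07 ± 0.42 (adjusted p = 0.0114). Of 26 cell cycle genes, 2 fell, or 6 adjusted over the list alone (adjusted p = 0.425 with an estimated correlation). Of 7 cytotoxic and NK cell genes, 2 fell by both adjustments (adjusted p = 0.293 with an estimated correlation).

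Several epithelial transcripts were higher in MEKi 1 than in Vehicle. Of 17 surface colonocyte genes, 5 rose, or 11 adjusted over the list alone (adjusted p = 0.35 with an estimated correlation). The carbonic anhydrase gene Car4 rose from 419 ± 96.0 to 1102 ± 488 CPM (log2 fold change 1.40 ± 0.43, adjusted p = 0.0432). Of 15 goblet cell genes, 3 rose, or 10 adjusted over the list alone (adjusted p = 0.339 with an estimated correlation). Atoh1, the transcription factor gene of secretory cells (chromosome 6, 64729125 to 64731245), rose from a mean of 34.3 to 76.5 CPM (log2 fold change 1.16 ± 0.22, adjusted p = 0.00995). Of 17 xenobiotic metabolism genes, 5 rose and 1 fell, or 9 and 1 adjusted over the list alone (adjusted p = 0.375 with an estimated correlation). The sulfotransferase gene Sult1a1 rose from 7.45 ± 1.47 to 129 ± 85.0 CPM (adjusted p = 0.0282). Of 17 fatty acid oxidation and PPAR target genes, 6 rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 0.293 with an estimated correlation). The oxidation enzyme gene Acadvl rose by 0.63 ± 0.13 (adjusted p = 0.0109), while Angptl4, a secreted lipase inhibitor, changed by -2.70 ± 0.57 (adjusted p = 0.0117). Of 12 smooth muscle genes, 2 rose, or 4 adjusted over the list alone. Of 12 endothelium genes, 1 fell, or 3 adjusted over the list alone. Of 16 unfolded protein and amino acid stress genes, 1 rose, or 1 rose and 2 fell adjusted over the list alone, with a median of -0.53. Of 12 enteroendocrine genes, 0 changed by either adjustment, with a median of 0.74. These 4 lists passed camera at the preset correlation and had adjusted p = 0.491 with an estimated correlation. Of 9 pancreas genes, 1 fell, or 9 adjusted over the list alone (camera adjusted p = 0.106), beside the 7027 CPM in Vehicle replicate 4. The other 3 Vehicle libraries held 0.85 to 2.92 CPM of pancreas transcripts, against 1.92 to 7.40 CPM in MEKi 1.

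The interferon and ERK groups gave few or no calls. None of 30 interferon-gamma response genes, 10 MHC class II genes or 16 ERK pathway output genes changed by either adjustment in edgeR, with median log2 fold changes of -0.05, -0.14 and -0.10 and camera adjusted p of 0.106, 0.489 and 0.575. The ERK feedback phosphatase gene Dusp6 had 57.6 ± 5.64 CPM in Vehicle and 65.4 ± 11.3 CPM in MEKi 1 (log2 fold change 0.19 ± 0.22, adjusted p = 0.589). Log2 fold changes were -0.14 ± 0.28 for Spry4 (adjusted p = 0.76), -0.51 ± 0.32 for Etv4 (adjusted p = 0.284) and -0.03 ± 0.35 for Etv5 (adjusted p = 0.963). Tnf was at -0.94 ± 0.50 (adjusted p = 0.211), Ifng at -1.25 ± 0.77 (adjusted p = 0.28) and Lcn2 at -2.11 ± 0.67 (adjusted p = 0.0505). Without MEKi 1 replicate 2, Tnf was at -1.64 (adjusted p = 0.0372), Ifng at -2.36 (adjusted p = 0.0841) and Lcn2 at -2.67 (adjusted p = 0.0257). Lcn2 also passed in 4 of the 8 alternative settings, DESeq2 (adjusted p = 0.0156), limma-voom with sample weights (0.00173), a mean of at least 5 CPM (0.043) and only the groups compared (0.025), and Tnf in 1 of 8, limma-voom (0.00923). Il17a, with 27 counts in Vehicle, 9 in MEKi 0.3 and 6 in MEKi 1, lay under the filter. In the edgeR fit with no filter it was at -1.87 ± 0.83 in MEKi 1 (adjusted p = 0.21).

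In all, 1565 genes differed between MEKi 1 and Vehicle, 898 higher and 667 lower, and 727 differed by more than 2-fold. Of the 33 lists tested, 17 passed camera at the preset correlation, 0 with an estimated correlation and 12 in the fry test. In data simulated for this comparison, 55.8% of genes changed by a log2 fold change of 1 were recovered, and 3.2% of those changed by 0.5. The simulated libraries held no shifts of a whole library, so recovery in the real ones may be lower. Without single libraries the count was 43 without MEKi 1 replicate 1, 2369 without MEKi 1 replicate 2, 220 without MEKi 1 replicate 3, 324 without Vehicle replicate 1, 812 without Vehicle replicate 2 and 128 without Vehicle replicate 4. The share of higher genes, 57.4% with all libraries, was under 50% without any 1 of 5 libraries: 34.9% without MEKi 1 replicate 1, 33.2% without MEKi 1 replicate 3, 34.3% without Vehicle replicate 1, 47.5% without Vehicle replicate 3 and 34.4% without Vehicle replicate 4. Of the 35 genes in this comparison followed under every setting that passed the threshold, 2, Aif1 and Atoh1, passed it without each library in turn, and 33 lost it without at least 1 of them. With no filter S100a9 (adjusted p = 0.053) and Car4 (adjusted p = 0.0945) fell short, Car4 also with library size only (adjusted p = 0.0514).

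**Figure D3:**
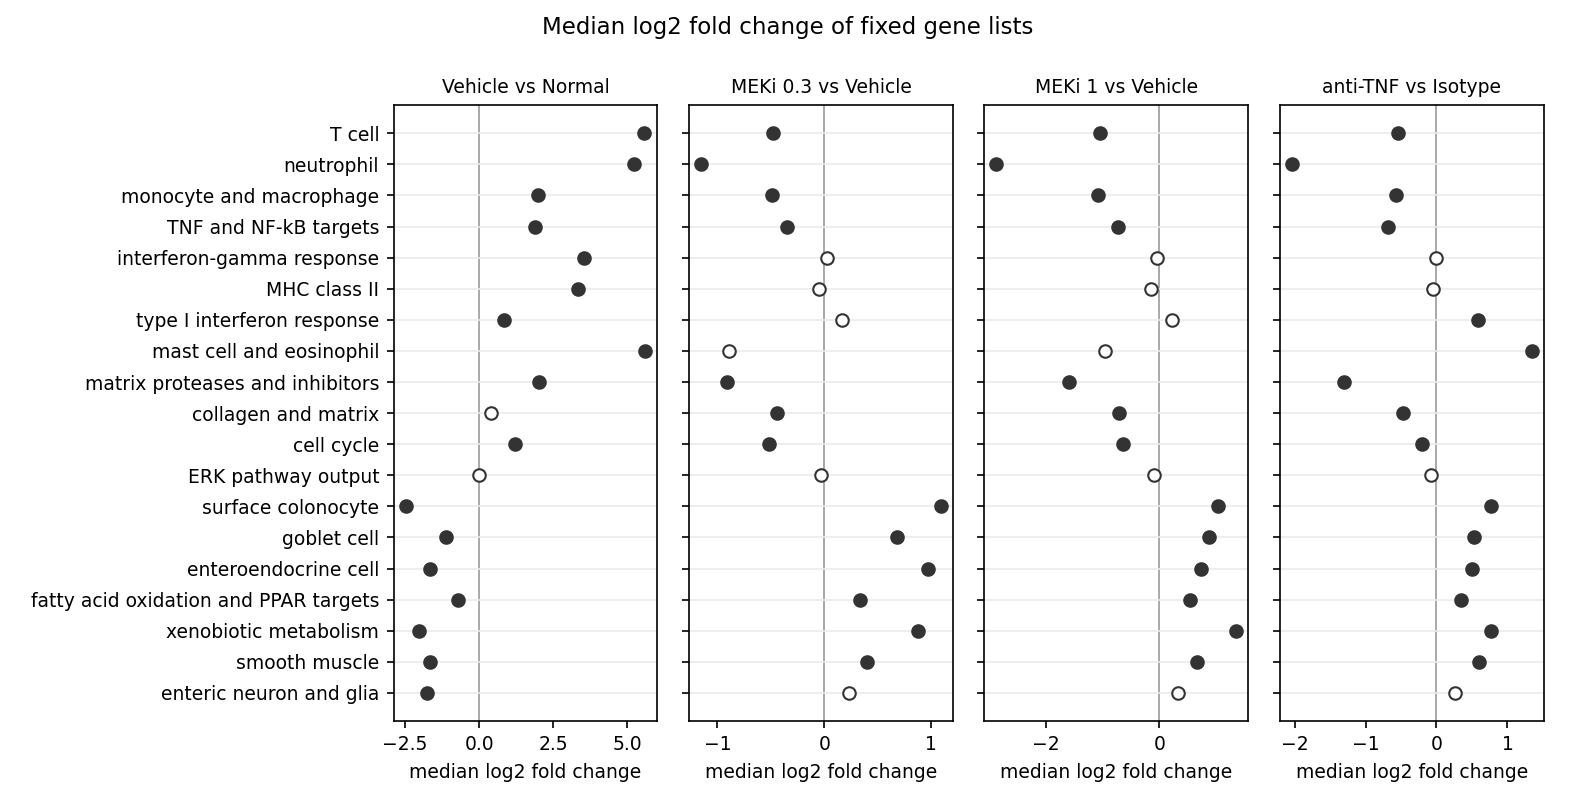
Median log2 fold change of the measured members of 19 fixed gene lists in 4 comparisons, with filled points for lists that passed camera at the preset correlation (adjusted over the 33 lists tested) and open points for the rest. In MEKi 1 against Vehicle the neutrophil median was -2.88 and the surface colonocyte median 1.04, and 0 lists of the 3 treatment panels passed with an estimated correlation.

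For the lower dose, MEKi 0.3 was compared with Vehicle. Banp, which encodes a nuclear matrix binding protein (chromosome 8, 121949750 to 122029258), rose from 9.10 ± 2.71 to 30.5 ± 10.2 CPM, a log2 fold change of 1.74 ± 0.25 (adjusted p = 0.00577). It was the 1 gene that passed in edgeR, with 92 genes by DESeq2 and 3303 by limma-voom with sample weights. At an unadjusted p under 0.05 there were 2639 genes, where chance gives 739 on average. That count was 1600 without MEKi 0.3 replicate 2 and 4325 without MEKi 0.3 replicate 4, and the excess was not tested. Genes that had passed at the higher dose had log2 fold changes of -0.83 ± 0.24 for Aif1 (adjusted p = 0.193), 0.90 ± 0.22 for Atoh1 (adjusted p = 0.18) and 3.66 ± 1.08 for Sult1a1 (adjusted p = 0.193). Both doses share the Vehicle libraries, so choosing genes at the higher dose favours values in the same direction here. Dusp6 was at 0.26 ± 0.22 (adjusted p = 0.532), Spry4 at 0.01 (adjusted p = 0.994), Etv4 at -0.79 ± 0.32 (adjusted p = 0.222) and Etv5 at -0.30 ± 0.35 (adjusted p = 0.656). Tnf was at -0.35 ± 0.49 (adjusted p = 0.721), Ifng at -0.29 ± 0.70 (adjusted p = 0.85) and S100a8 at -1.45 ± 0.71 (adjusted p = 0.288). Lcn2 did not pass in edgeR, with -2.20 to -0.84 when 1 library was left out. It passed without MEKi 0.3 replicate 4 (adjusted p = 0.0436) and with limma-voom (adjusted p = 0.00983). Of 17 fatty acid oxidation and PPAR target genes, 0 changed over all genes, and 6 were higher and 1 lower adjusted over the list alone. Of 12 enteroendocrine genes, 0 changed over all genes and 3 were higher adjusted over the list alone. Of the 33 lists, 16 passed camera at the preset correlation, among them neutrophil with a median log2 fold change of -1.15, cell cycle with -0.52 and surface colonocyte with 1.09. Without MEKi 0.3 replicate 4 the neutrophil median was -2.01 and the cell cycle median -0.89, and without MEKi 0.3 replicate 2 the surface colonocyte median was 0.52. All 16 had adjusted p of 0.493 to 0.537 with an estimated correlation. Log2 fold changes correlated with transcript length (Spearman 0.265 across 12175 genes, which are not independent replicates), and the longest minus shortest difference was -0.10 ± 0.10 in MEKi 0.3 against -0.38 ± 0.12 in Vehicle. Without MEKi 0.3 replicate 4 the count was 1130 genes, among them Aif1 (adjusted p = 0.0281), Atoh1 (adjusted p = 0.0261) and Sult1a1 (adjusted p = 0.0344), and without Vehicle replicate 4 it was 0. With only the groups compared Banp fell short (adjusted p = 0.0899), while Atoh1 and Sult1a1 passed with DESeq2 (adjusted p = 0.029 and 0.0215) and, like Aif1 and S100a8, with limma-voom (adjusted p of 0.00463 to 0.0198 for the 4).

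The doses themselves were compared to ask whether the higher one changed more. No gene passed in edgeR between MEKi 1 and MEKi 0.3, with 641 genes at an unadjusted p under 0.05, where chance gives 739, and with 2 genes by DESeq2 and 0 by limma-voom with sample weights. The smallest p belonged to Nt5c1a, a nucleotidase gene with 3 counts in MEKi 1, whose count was lower there by a ratio of 11.6 (95% counting interval 3.70 to 58.4, adjusted p = 0.926). Gpr18 was at -1.55 ± 0.34 (adjusted p = 0.926), Gabrp at -1.31 ± 0.32 and Il1b at -1.60 ± 0.57 (adjusted p = 1 for both). Dusp6 was at -0.07 ± 0.22, Tnf at -0.60 ± 0.51 and S100a8 at -1.18 ± 0.73, each with an adjusted p of 1. Spry4 was at -0.146 ± 0.278, Etv4 at 0.277 ± 0.329 and Etv5 at 0.267 ± 0.352. Ifng was at -0.965 ± 0.788 and Lcn2 at -0.948 ± 0.658, and none of these passed. Tnf was at -1.29 without MEKi 1 replicate 2 and -0.21 without MEKi 0.3 replicate 4, and without the latter S100a8 was at -0.37 and Il1b at -1.01. Neutrophil genes had a median of -1.57, monocyte and macrophage genes of -0.52 and T cell genes of -0.58, with 0 members changed over all genes and 1, 0 and 0 adjusted over the list alone. These lists passed camera at the preset correlation and had adjusted p = 0.212 with an estimated correlation. The neutrophil median was -0.57 without MEKi 0.3 replicate 4, and the monocyte and macrophage median -0.29 without MEKi 1 replicate 4. Without MEKi 0.3 replicate 3, 1 gene passed, Nt5c1a (adjusted p = 0.0311). In simulated data for this comparison, 90.2% of genes changed by a log2 fold change of 2 were recovered and 50.6% of those changed by 1. Those data held no library that stood apart as a whole, so recovery in the real libraries may be lower. Clec4e, at -3.41 ± 0.92, did not pass between the doses.

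Anti-TNF was compared with its isotype control to ask what TNFa blockade changed. Gpr84, a receptor for medium-chain fatty acids on myeloid cells, fell from 4.58 ± 2.11 to 0.134 ± 0.119 CPM, a log2 fold change of -4.92 ± 0.65 (adjusted p = 0.000969). Mcemp1, a myeloid membrane protein gene, fell from 6.87 ± 2.54 to 0.959 ± 0.435 CPM (log2 fold change -2.81 ± 0.49, adjusted p = 0.0403). Klf11, a transcription factor gene, rose from 3.84 ± 0.929 to 9.68 ± 3.04 CPM (log2 fold change 1.32 ± 0.24, adjusted p = 0.0453). These were the 3 genes that passed, with 77 genes by DESeq2 and 45 by limma-voom with sample weights. At an unadjusted p under 0.05 there were 1653 genes, where chance gives 739 on average. That count was 913 without anti-TNF replicate 4 and 2255 without anti-TNF replicate 1, and the excess was not tested. Gpr84 and Mcemp1 lay under the level set for named genes and were chosen after their values were seen. Gpr84 passed without each library in turn, and Klf11 only without Isotype replicate 4. Mcemp1 was lost without anti-TNF replicates 1, 2 and 3 and without Isotype replicates 1 and 3, where 1 gene passed each time, and 34 genes passed without Isotype replicate 4. With only the groups compared 0 genes passed in edgeR, with 1303 at an unadjusted p under 0.05 (adjusted p = 0.0719 for Gpr84, 0.107 for Mcemp1 and 0.304 for Klf11). Klf11 fell short in 5 of the 8 alternative settings, among them library size only (adjusted p = 0.072), no filter (0.0713) and a mean of at least 5 CPM (0.06).

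No list member passed over all genes under anti-TNF in edgeR, and the counts below rest on adjustment over the list alone. Of 16 neutrophil genes, 11 were lower adjusted over the list alone, with a median log2 fold change of -2.04. All 5 red blood cell genes were lower adjusted over the list alone too, with a median of -1.60 (adjusted p = 0.261 with an estimated correlation), or -0.38 over the 4 still tested without Isotype replicate 3, which held 254.3 CPM of their transcripts, against 27.2 to 74.1 CPM in the other Isotype libraries and 19.5 to 66.1 CPM in anti-TNF. Fpr2, a neutrophil chemotaxis receptor, was at -3.06 ± 0.57 and Clec4e at -4.89 ± 0.91 (adjusted p = 0.0632 for both, and 0.0273 for both without Isotype replicate 4). With DESeq2, Fpr2 had adjusted p = 9.02e-05 and Clec4e 0.00082. Of 25 TNF and NF-kB targets, 12 were lower adjusted over the list alone, with a median of -0.68, and the lymphotoxin gene Ltb was at -1.19 ± 0.27 (adjusted p = 0.164, and 0.0148 with DESeq2). Of 7 mast cell and eosinophil genes, 2 were higher adjusted over the list alone, with a median of 1.34. The neutrophil, TNF and NF-kB and mast cell lists also passed the fry test at adjusted p = 0.0312, and had adjusted p = 0.0905 for neutrophil, 0.0947 for TNF and NF-kB and 0.0905 for mast cell and eosinophil genes with an estimated correlation. Of 23 type I interferon response genes, 22 had positive log2 fold changes with a median of 0.59, and 1 was higher adjusted over the list alone (adjusted p = 0.2 with an estimated correlation). That median was 0.29 without anti-TNF replicate 4. Dusp6 was at 0.11 ± 0.21 (adjusted p = 0.887), Spry4 at -0.57 ± 0.26 (adjusted p = 0.422), Tnf at -0.68 ± 0.48 (adjusted p = 0.625), Ifng at 0.29 ± 0.66 (adjusted p = 0.904) and Lcn2 at -1.31 ± 0.65 (adjusted p = 0.46). S100a8, Etv4 and Etv5 did not pass either. With 1 library left out they were at -1.543 to -0.716, -0.256 to 0.304 and 0.041 to 0.444. All 9 pancreas genes were lower adjusted over the list alone (adjusted p = 0.208 with an estimated correlation), with 5336 CPM of pancreas transcripts in Isotype replicate 1 and 12.85 to 131.76 CPM in the other 3 Isotype libraries. Of the 33 lists, 23 passed at the preset correlation and 0 with an estimated correlation. For 4 of the 8 antibody libraries a second table of the series carries the name of the other antibody group. A fit under its names for all libraries gave 0 genes, with 291 at an unadjusted p under 0.05. Those names also mix the Normal, Vehicle and MEKi groups, so this fit cannot tell what the 4 antibody names alone would change. On the antibody libraries where both agree, Isotype replicates 1 and 2 and anti-TNF replicates 3 and 4, 0 genes passed, with 1862 at an unadjusted p under 0.05.

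A score of colitis asked how far each treatment moved libraries toward Normal. It was the mean log2 CPM of genes higher in colitis minus that of genes lower, with genes taken from the control arm outside each comparison, 1368 higher and 1526 lower from Isotype against Normal and 1569 and 1674 from Vehicle against Normal. Vehicle had a score of 1.81 ± 0.24, MEKi 1 of 0.16 ± 0.70 and Normal of -2.07 ± 0.17. The difference of -1.64 ± 0.37 for MEKi 1 was 42.3% of the gap to Normal, with 4 of 4 libraries below every Vehicle library (two-sided exact permutation p = 0.0286, the smallest that 70 labelings give; adjusted p = 0.114 over 4 tests). MEKi 0.3 differed from Vehicle by -1.02 ± 0.42 (exact permutation p = 0.143, adjusted p = 0.19), with 3 of 4 libraries below every Vehicle library. MEKi 1 differed from MEKi 0.3 by -0.62 ± 0.54 (exact permutation p = 0.286, adjusted p = 0.286), and by -0.22 without MEKi 0.3 replicate 4, -0.40 without MEKi 1 replicate 1 and -0.93 without MEKi 1 replicate 2. Anti-TNF differed from Isotype by -0.98 ± 0.56 (exact permutation p = 0.143, adjusted p = 0.19), with 2 of 4 libraries below every Isotype library, and by -0.51 without anti-TNF replicate 4. No score difference passed after adjustment. With 4 tests, a lone comparison at the smallest exact p has an adjusted p of 0.114, so full separation of the MEKi 1 libraries alone could not pass.

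**Figure D4:**
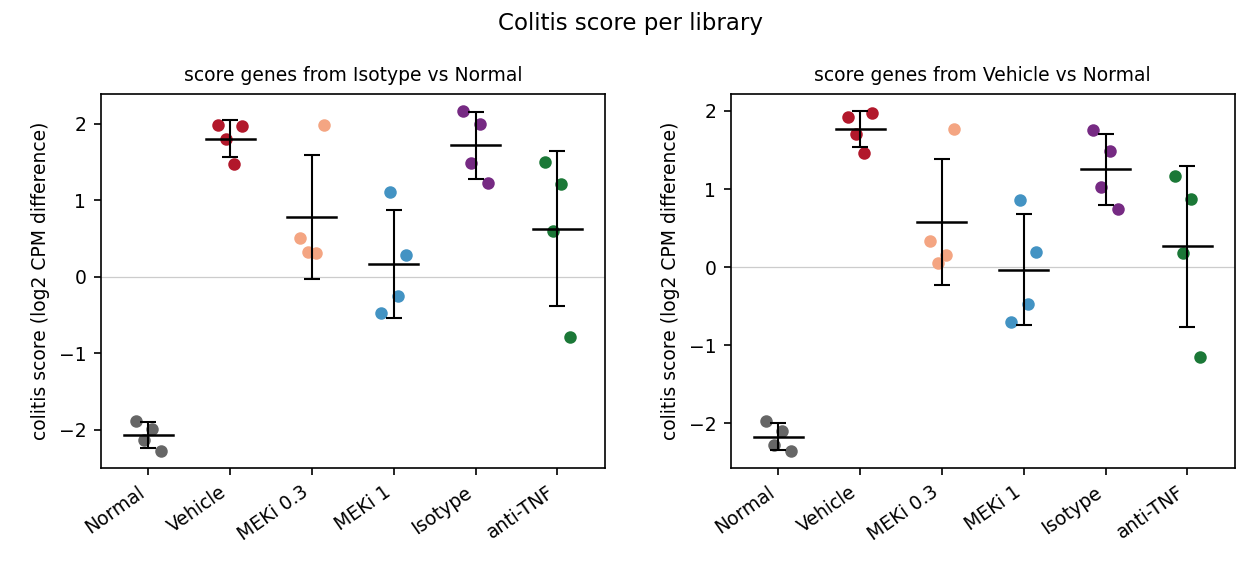
Colitis score per library, in log2 CPM, with score genes from Isotype against Normal on the left and from Vehicle against Normal on the right. Points are libraries, bars the group mean and error bars 1 SD, and groups whose own libraries chose the genes share them with the score. MEKi 1 had a mean of 0.16 on the left, and MEKi 0.3 replicate 4 lay at 1.98.

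Of the 2894 genes changed by more than 2-fold in Isotype against Normal, 698 moved back in MEKi 1 against Vehicle, where independent lists would share 154.5, and 4 moved further. That count was 23 without MEKi 1 replicate 1, 1084 without MEKi 1 replicate 2, 121 without MEKi 1 replicate 3, 170 without Vehicle replicate 1, 371 without Vehicle replicate 2 and 75 without Vehicle replicate 4. They comprised 361 genes higher in colitis and 337 lower, and 90.7% of the 2894 had the opposite sign whatever their p. Of the 3243 genes from Vehicle against Normal, 2 moved back with anti-TNF, where independent lists would share 0.3, and 88.8% had the opposite sign. Genes are not independent, so a chance shift between groups of 4 libraries can move many of them at once. The counts for independent lists do not allow for that, and neither share of opposite signs was tested. Without Isotype replicate 4, 29 moved back, and 1 did without anti-TNF replicates 1, 2 or 3 or Isotype replicates 1 or 3. The log2 fold changes of MEKi 1 and anti-TNF, which share no library, were compared across 14773 genes, which are not independent replicates. Their Pearson correlation was 0.716 and their Spearman correlation 0.636, with the same sign in 73.3%. Leaving out 1 library gave Pearson values of 0.551 to 0.75, with a leave-1-out SE of 0.213. No value for unchanged groups was simulated for this pair. MEKi 1 and MEKi 0.3 share the Vehicle libraries and had a Pearson correlation of 0.83 and the same sign in 84.0%. On log2 CPM means their correlation was 0.861, against 0.493 for simulated unchanged groups and 0.542 to 0.7 with the Vehicle libraries split between them. Their covariance was 0.253, against 0.0504 in the simulations, a difference of 0.203. Genes were drawn independently in these simulations, without shifts of whole libraries. Unchanged real groups could therefore correlate more strongly than the simulated ones.

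The effect of MEKi 1 was tested against the effect of anti-TNF directly. Banp differed by 2.64 ± 0.35 (adjusted p = 0.00119), with 9.10 ± 2.71 CPM in Vehicle, 33.8 ± 6.60 in MEKi 1, 16.9 ± 4.07 in Isotype and 9.99 ± 1.29 in anti-TNF. Klf11 differed by -2.44 ± 0.35 (adjusted p = 0.00207). These 2 genes passed, and did so without each of the 16 libraries in turn, with 729 at an unadjusted p under 0.05, where chance gives 739, and with 7 genes by DESeq2 and 1288 by limma-voom with sample weights. Without Isotype replicate 3, 5 genes passed. Under the second table's names for all libraries, 0 genes passed in edgeR (876 at an unadjusted p under 0.05). Banp was then at -0.75 ± 0.71 (adjusted p = 0.702) and Klf11 at -0.18 ± 0.62 (adjusted p = 0.919). Those names also mix Normal, Vehicle and MEKi libraries, so they cannot tell what the 4 antibody libraries undecided by the counts would change. No fit exchanged those 4 of the 8 antibody libraries alone. With libraries thinned to equal depth, 1 gene passed. The mast cell and eosinophil list had a median difference of -2.40, with 5 of 7 genes lower adjusted over the list alone and 0 over all genes (adjusted p = 0.0196 with an estimated correlation). Of 33 lists, 7 passed at the preset correlation, and the other 6 had adjusted p of 0.81 to 0.821 with an estimated correlation.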

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

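The tests on transcript length, GC content, depth and other splits, and the test for a male library, were chosen only after the results were seen. A sample was singled out when it lay far from the other 3 of its group by Dixon's test. That happened in 23 of 290 groups of values, where chance gives about 14.5 (1 in 20).

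The control arms, Isotype and Vehicle, differed in 442 genes. Removing the GC content trend left 456 genes and thinning all libraries to 1 depth left 237, against a highest value of 32 among other splits of the same libraries, which argues against either as the whole cause. Removing the transcript length trend left 29, of which 23 were among the 442. The median absolute log2 fold change of the 442 went from 0.75 to 0.43, with median SEs of 0.17 and 0.16, so the calls ended because the changes shrank. A length bias between libraries may therefore account for most of the 442, while an effect of antibody against methylcellulose stays open and untested.

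Genes changed at the higher MEK inhibitor dose numbered 1565. They numbered 1383 with the length trend removed and 1743 with the GC content trend removed, against at most 133 in other splits, which argues against either trend as the whole cause. Log2 fold changes did correlate with transcript length (Spearman 0.232 across 12175 genes, which are not independent replicates). With the length trend removed, 1247 of the 1565 stayed past the threshold, and the share of higher genes was 51.6%, against 57.4%. Without the pancreas-rich libraries 391 genes passed, and 128 without Vehicle replicate 4 alone, but in each case 2 of 35 splits of the remaining libraries gave as many, the real one and one with MEKi 1 replicate 2 among Vehicle, which gave 1004 and 705 and points to a structure of the samples. The log2 fold changes of the 1559 called genes still tested correlated at 0.996 with those of the fit without pancreas-rich libraries, which decides nothing, since leaving out any 1 of the other 7 libraries gave 0.994 to 0.997. The median absolute log2 fold change of these genes was 0.94 in the main fit and 0.877 without the pancreas-rich libraries, with median SEs of 0.254 and 0.261. It was 0.88 without Vehicle replicate 4 alone (median SE 0.274), and 100% of the genes kept their sign in each case. The called genes thus kept most of their size with Vehicle replicate 4 left out. This argues against its pancreas tissue as the whole cause for these genes, and says nothing on other causes. They were chosen in the fit with every library, which shares the remaining ones, and leaving out MEKi 1 replicate 1 gave 0.877 too. Chance differences among the remaining libraries are therefore not excluded. A part from pancreas tissue or transcript length, the drug, its microparticle carrier, the share of immune cells and unrecorded differences in sampling stay open.

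Isotype replicate 3 had 7.0 CPM of Xist, against 151.8 to 365.7 in the other libraries. Its summed count of 4 Y chromosome genes was 0, which argues against a male animal. The longest transcripts had a median log2 ratio of -0.042 to the other libraries, inside their range of -0.36 to 0.33, which argues against a loss of long transcripts. Genes escaping X inactivation had a median log2 ratio of -0.61, the lowest of 24 libraries, with -0.24 to 0.35 in the others. Of its 6 genes, Ddx3x at -0.005 and Pbdc1 at -0.233 lay above the rest, which were at -0.977 to -0.505. Loss of 1 X chromosome is a candidate explanation, found and tested on the same data, and a strain or tissue difference was not tested.

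Against other splits of the same libraries, the real split gave the most genes for Vehicle against Normal (6853, highest other 0, 1 of 35 splits as large). It did so too for Isotype against Normal (6085, 25, 1 of 35), MEKi 1 against Vehicle (1565, 133, 1 of 35) and Isotype against Vehicle (442, 32, 1 of 35). This argues against chance there but cannot exclude it, since 1 of 35 is the smallest share possible, without adjustment over the 8 comparisons. Without Vehicle replicate 4, 2 of 35 splits for MEKi 1 against Vehicle, the real one among them, gave at least the real count. For anti-TNF against Isotype the real split gave 3 genes and the others 0 (1 of 35, the smallest share possible). The counts cannot decide the labels of 4 of these 8 libraries, though the pattern of names favours those used. With only the groups compared 0 genes passed in edgeR, so chance is not taken as excluded for the 3 genes. For the difference of effects, 4 of 100 drawn splits gave at least the real count of 2 genes. The highest other value of 1928 came from a split that exchanged all MEKi 1 and Vehicle libraries, and so held the whole difference between them. Such splits are not free of effect, so this share does not speak for the 2 genes. For MEKi 0.3 against Vehicle (1 gene, 2 of 35 splits as large) the splits do not argue against chance. The split exchanging Vehicle replicate 3 and MEKi 0.3 replicate 4 gave 248 and points to a structure of the samples. Among the 8 splits that part all 4 same-numbered pairs, the real one alone reached 1 gene, with 0 in the others. For MEKi 1 against MEKi 0.3 the real count was 0 in edgeR (641 genes at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom), which all 35 splits must reach (highest other 2), so they decide nothing.

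The effects of MEKi 1 and anti-TNF differed, by a test of the difference itself, in 2 genes, Banp and Klf11, and in the mast cell and eosinophil list (adjusted p = 0.0196 with an estimated correlation). Pancreas transcripts stood at 7027 CPM in Vehicle replicate 4 and 5336 CPM in Isotype replicate 1, against 0.85 to 131.8 CPM in the other 22 libraries. Mitochondrial counts were 4.59% in Isotype replicate 3, against 1.99% to 2.18% in its group. MEKi 1 replicate 4 had a longest minus shortest transcript difference of -0.41. MEKi 0.3 replicate 4 stood apart from its group in the colitis scores, 1.98 with Isotype genes and 1.77 with Vehicle genes, and in Aif1 (34.2 CPM) and Atoh1 (35.7 CPM). Vehicle replicate 4 stood apart in Banp (5.08 CPM) and Gm7206 (39.8 CPM), Isotype replicate 3 in Dusp6 (44.6 CPM), Luc7l (44.1 CPM) and Mcpt4 (0.347 CPM), and MEKi 1 replicate 2 in Dusp6 (82.3 CPM), Fpr2 (5.86 CPM) and Zg16 (1230 CPM). Single values stood apart for Csf3r in Normal replicate 2 (0 CPM), Etv4 in Vehicle replicate 1 (20.2 CPM), Fpr2 in anti-TNF replicate 4 (0.787 CPM), Gstm1 in Vehicle replicate 3 (103 CPM), Mcpt1 in Normal replicate 4 (1.53 CPM), and Slc30a10 in Isotype replicate 2 (0.236 CPM) and Vehicle replicate 2 (0.19 CPM).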

How the results depend on the processing

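The alternatives on column names, labellings, length, GC content, thinned libraries and pancreas-rich libraries, the counts of genes moved back and the list medians without 1 library, and the tests they give, were chosen only after the results were seen. Of 2257 values of named genes under other settings, 1995 kept direction and side of the threshold, 185 fell short of it, 52 newly passed it and 25 changed sign. The cause was not tested unless stated. Counts of genes past the threshold follow. DESeq2 gave 92 for MEKi 0.3 against Vehicle, 2 for MEKi 1 against MEKi 0.3, 77 for anti-TNF against Isotype, 789 for Isotype against Vehicle and 7 for the difference of effects. limma-voom with sample weights gave 3303, 0, 45, 2916 and 1288 for these, and 4807 for MEKi 1 against Vehicle. With no filter the counts were 773 for MEKi 1 and 3 for MEKi 0.3 against Vehicle and 267 for Isotype against Vehicle. With a mean of at least 5 CPM anti-TNF gave 0, where Gpr84 is no longer tested. With only the groups compared MEKi 0.3 and anti-TNF gave 0 each. With library size only, 47.2% of the genes of MEKi 1 against Vehicle were higher, against 57.4% as reported. The table's column names gave 0 for Vehicle against Normal, 262 for Isotype against Normal, 0 for MEKi 1, MEKi 0.3 and anti-TNF against their controls, 162 for Isotype against Vehicle and 0 for the difference of effects. The libraries on which both labellings agree gave 0 for anti-TNF. A length offset gave 29 and a length and GC offset 35 for Isotype against Vehicle, and a GC offset 5 for the difference of effects. Thinned libraries, with fewer counts, gave 761 for MEKi 1, 3 for MEKi 0.3, 1 for anti-TNF, 237 for Isotype against Vehicle and 1 for the difference of effects. Without pancreas-rich libraries, with fewer samples, 391 genes passed for MEKi 1 and 154 for Isotype against Vehicle. Genes moved back numbered 1085 for MEKi 1 with no minimum fold change and 67 for anti-TNF with DESeq2. Of 264 list tests, 130 passed as reported, 9 with an estimated correlation and 70 with fry.

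Leaving out 1 library gave 5983 to 6614 genes for Vehicle against Normal, 4901 to 5798 for Isotype against Normal, 43 (without MEKi 1 replicate 1) to 2369 (without MEKi 1 replicate 2) for MEKi 1 against Vehicle, 0 (without Vehicle replicate 4) to 1130 (without MEKi 0.3 replicate 4) for MEKi 0.3, 0 to 1 (without MEKi 0.3 replicate 3) between doses, 1 (without anti-TNF replicates 1, 2 or 3 or Isotype replicates 1 or 3) to 34 (without Isotype replicate 4) for anti-TNF, 128 (without Isotype replicate 4) to 493 for Isotype against Vehicle and 2 to 5 (without Isotype replicate 3) for the difference of effects. Genes moved back numbered 23 (without MEKi 1 replicate 1) to 1084 (without MEKi 1 replicate 2) for MEKi 1 and 1 to 29 (without Isotype replicate 4) for anti-TNF. The other libraries that moved a count by more than 1.5 times are named in the comparisons. Genes that changed sign were not past the threshold. For MEKi 1 against Vehicle, leaving out 1 library gave -0.414 to 0.081 (without Vehicle replicate 2) for Spry4 and -0.403 to 0.181 for Etv5, positive without MEKi 1 replicates 1 or 4 or Vehicle replicate 4, and Etv5 was 0.232 with limma-voom. For MEKi 0.3, Spry4 was -0.002 with RLE factors and with DESeq2, -0.008 with library size only and -0.175 to 0.226 without 1 library, negative without MEKi 0.3 replicates 2 or 4 or Vehicle replicates 1 or 4, and Ifng was -1.074 to 0.104, positive without MEKi 0.3 replicates 2 or 3 or Vehicle replicate 4. Between doses, Dusp6 was -0.237 to 0.078 (without MEKi 0.3 replicate 2), Etv5 -0.1 (without MEKi 1 replicate 3) to 0.517 and Lcn2 -1.518 to 0.096 (without MEKi 0.3 replicate 4). For anti-TNF, Dusp6 was -0.104 to 0.208, negative without anti-TNF replicate 3 or Isotype replicate 3, Ifng -0.037 to 0.591, negative without anti-TNF replicate 1 or Isotype replicate 2, and Etv4 -0.256 to 0.304, positive without anti-TNF replicate 2 or Isotype replicate 1, and 0.223 with limma-voom.

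With the replicate block the counts were 6665, 5882, 1149, 1, 0, 2, 375 and 2 in the order Vehicle and Isotype against Normal, MEKi 1 and MEKi 0.3 against Vehicle, between doses, anti-TNF, Isotype against Vehicle and the difference of effects. Under it 8 named genes of MEKi 1 against Vehicle (S100a8, S100a9, Cxcl2, Saa3, Cyp2f2, Gsdmc3, Tgm3 and Car4) had adjusted p of 0.0512 to 0.0706, and Klf11 in anti-TNF against Isotype had 0.0924. Outside MEKi 0.3 against Vehicle, no comparison had all 4 same-numbered pairs above 0.1, so the numbers were not taken as pairs. For anti-TNF against Isotype the correlations were 0.216, 0.086, 0.142 and 0.342, with 5 of 8 libraries closest to their own number, and for Isotype against Vehicle 0.116, 0.165, 0.104 and -0.395, with 3 of 8, hints from the data that leave a shared origin open. The rest had -0.248 to 0.223. Depth limits genes of few counts, such as Il17a with 39 counts at most per group.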

Other observations

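The tests of Il17a with no filter were chosen only after its counts were seen, and the rest of this part reports values alone. Immunoglobulin transcripts, made by B lineage cells that SCID mice lack, were summed over 319 genes. They took 5.8 to 33.2 CPM in Normal, 1077 to 8428 CPM in Vehicle, 48.3 to 4771 CPM in MEKi 0.3, 273.6 to 3617 CPM in MEKi 1, 175.9 to 3861 CPM in Isotype and 57.2 to 2906 CPM in anti-TNF. Values of single V genes are uncertain, since near-identical copies can share reads.

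Summed counts of Il17a, a T helper cytokine, were 0 in Normal, 27 in Vehicle, 9 in MEKi 0.3, 6 in MEKi 1, 29 in Isotype and 39 in anti-TNF, under the filter. In the edgeR fit with no filter it was at 0.44 ± 0.65 in anti-TNF against Isotype (adjusted p = 0.914) and at -1.52 ± 0.77 in MEKi 0.3 against Vehicle (adjusted p = 0.472). Mitochondrial transcripts took 4.74 ± 1.29% of counts in Normal and 2.90 ± 0.27% in Vehicle (SD, n = 4).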
